A study of Rattus norvegicus with 36 samples.

How the data were processed

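Total RNA of rat dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, was measured on Affymetrix RG_U34 arrays, which come as 3 chip types (A, B and C) with different probe sets. The labels describe 6 pools of ganglia, 3 conditions at 2 times (28 and 50 days after surgery): L5 ganglia of rats whose L5 spinal nerve had been ligated, the neighbouring L4 ganglia of operated rats, and ganglia of sham-operated rats, which per the labels hold L4 and L5 ganglia together. Pools were made from 30 rats where the labels give a number. Each pool was put on 2 arrays of each chip type, which gives 36 arrays. The design text of the series states that pooling left no biological replication on the arrays.

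The deposited values are intensity signals on a linear scale, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. In the deposited tables the intensity of each array had been brought to a common level: the mean without the highest and lowest 2% of values lay between 150.07 and 150.21 on all 36 arrays. No detection calls were used here, so a dim probe set cannot be called absent. The number of arrays limits the precision. Median signals ran from 50.6 to 72.8 on chip A, 70.6 to 86.7 on chip B and 79.9 to 91.8 on chip C. The 2 arrays of a pool correlated at r = 0.882 to 0.958 across tested probe sets.

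Array values were scaled to the same trimmed mean within a chip type, which changed almost nothing, and transformed to log2(signal + pseudocount). The pseudocount was the 20th percentile of all signals of a chip type (12.8, 17.7 and 20.2 for A, B and C), so fold changes of dim genes are understated. Control probe sets were left out, as were probe sets whose mean lay under the 40th percentile of their chip type, which left 15721 probe sets. The 2 arrays of a pool were averaged, because they share RNA. limma 3.58.1 in R 4.3.3 was then fitted to the 6 pools of each chip type with condition and day as terms (lmFit, and eBayes with an intensity trend), and p-values were adjusted by Benjamini-Hochberg over all 3 chip types at a threshold of 0.05. The pools of 28 and 50 days stand as the 2 replicates of a condition, with 2 residual degrees of freedom. A gene whose response differs between the days therefore has a larger residual and is less easily called. At either day alone there is 1 pool per condition and no test.

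Gene names came from the platform annotation, and symbols were checked against a RefSeq gene table of assembly GRCr8, used for names alone; 0 symbols needed an update. Of the probe sets, 7006 on A, 5351 on B and 5821 on C had 1 gene, 308, 38 and 45 had several and were not named, and 1426, 3343 and 2864 had none. Before the data were examined, 32 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took, among probe sets past the threshold with 1 gene and the same sign at both days, the 12 largest rises and 12 largest falls for each ganglion against sham (8 and 8 for L5 against L4, 5 and 5 for the days), filled to 5 by lowest p where fewer passed; up to 4 members of each list that passed in either ganglion against sham; and 12 genes named in any case. A gene with several probe sets is given by its brightest one among those called, or among those tested for list members and for genes named in any case. The lists hold neuropeptides, sodium, potassium, calcium, and transduction and pacemaker channels, G protein-coupled, and GABA and glutamate receptors, neurotrophic factors, axon injury, immediate early and heat shock genes, cytoskeleton, synaptic vesicle release, cholesterol synthesis, oxidative phosphorylation, extracellular matrix, complement, antigen presentation, cytokines, sympathetic genes, and markers of general, large-diameter, peptidergic and non-peptidergic neurons, macrophages, T cells, satellite glia, myelinating and repair Schwann cells, blood, fat, vessel and skeletal muscle cells. Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01 and again with an estimated correlation. With an estimated correlation camera takes its p-values from the 2 residual degrees of freedom of the fit. A pass is then close to excluded beforehand, so a list that does not pass that way is not shown to be unchanged. The preset value in turn is an assumption about these genes.

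The code was tested on simulated data for L5 against sham, with 200 of 15721 probe sets changed and 20 draws. With spreads drawn from the distribution that limma assumes, 81.6% of changes of 2 on the log2 scale and 23.0% of changes of 1 were recovered, and 5.29% of calls were false on average. With spreads taken from these arrays, 84.2% and 40.3% were recovered and 10.9% of calls were false on average (3.73% to 16.5%), so more than the nominal share of the calls below may be false. In these draws, with no day effect present, up to 9 probe sets were called for the day. Gene lists were checked in the first draw of each simulation only, where 3 of 3 shifted lists were found, with 0 others. Probe sets were simulated independently of each other, so this cannot show how many lists would pass falsely with correlated genes.

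An array of chip B has a title that says 28 days and a description that says 50 days. It was grouped by its title, and left out or counted as 50 days in alternatives. Other alternatives changed the scaling, pseudocount, filter, variance prior, multiple testing, treatment of the 2 arrays of a pool, and the pools used. Scaling to the bacterial hybridisation controls was chosen after the data were seen. So was leaving out the least correlated array of each chip type, the one with the lowest mean correlation with arrays of other pools. The controls were first taken all together (9 probe sets); a version without the 2 Cre probe sets was added after Cre was seen to differ between arrays of chip C, and both are reported.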

Results

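Expression was measured in 6 pools of rat dorsal root ganglia, from 3 conditions at 28 and at 50 days. The L5 ganglia came from rats with a ligated L5 spinal nerve, a model of neuropathic pain. The neighbouring L4 ganglia came from operated rats, and their own nerve was not ligated. The sham pools held L4 and L5 ganglia together, so differences between normal L4 and L5 ganglia are part of each comparison with sham, and also of L5 against L4. Each pool was measured on 2 arrays of each of 3 chip types. Differences are on the log2 scale with the standard error (SE) of the limma fit, with n = 2 pools per condition. They are relative to the mean level of an array, since every array had been scaled to the same mean.

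In L5 ganglia the neuropeptides Vip, Npy and Gal rose, as did Atf3, a transcription factor induced by axon injury, while the sodium channels Scn11a, Scn10a and Scn1a fell. Vip was higher than in sham by 2.72 ± 0.24 (6.61-fold, adjusted p = 0.0045) and Npy by 2.03 ± 0.22 (4.08-fold, adjusted p = 0.0058). Atf3 was higher by 1.52 ± 0.21 (2.87-fold, adjusted p = 0.015) and Gal 2.83-fold (SE 0.26 on the log2 scale, adjusted p = 0.030). The sodium channels Scn11a (-1.38 ± 0.19, adjusted p = 0.015), Scn10a (-1.34 ± 0.22, adjusted p = 0.023) and Scn1a (-1.35 ± 0.23, adjusted p = 0.030) were lower. All 7 genes had the same sign at both days. Without the sham pool of 28 days Gal (1.20, adjusted p = 0.16), Scn10a (-1.12, adjusted p = 0.16) and Scn1a (-1.16, adjusted p = 0.15) missed the threshold.

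In all, 123 of 15721 probe sets passed in L5 against sham, 37 higher and 86 lower. In simulated data with the spreads of these arrays, 10.9% of calls were false on average. The count was 31 without the sham pool of 28 days and 77 without that of 50 days. It was 450 and 453 without the L4 pools of 28 and 50 days, and 478 and 621 without the L5 pools. With only the first or only the second array of each pool, 1 and 2 probe sets passed, and without the intensity trend of the variance prior 4 passed. Scaling also moved the count and its split, to 17 higher and 25 lower with quantile normalization and to 46 and 377 with median centring. With arrays scaled to their hybridisation controls the split was 33 and 2834, and the median of all probe sets moved to -0.44 from 0.04.

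**Figure D1:**
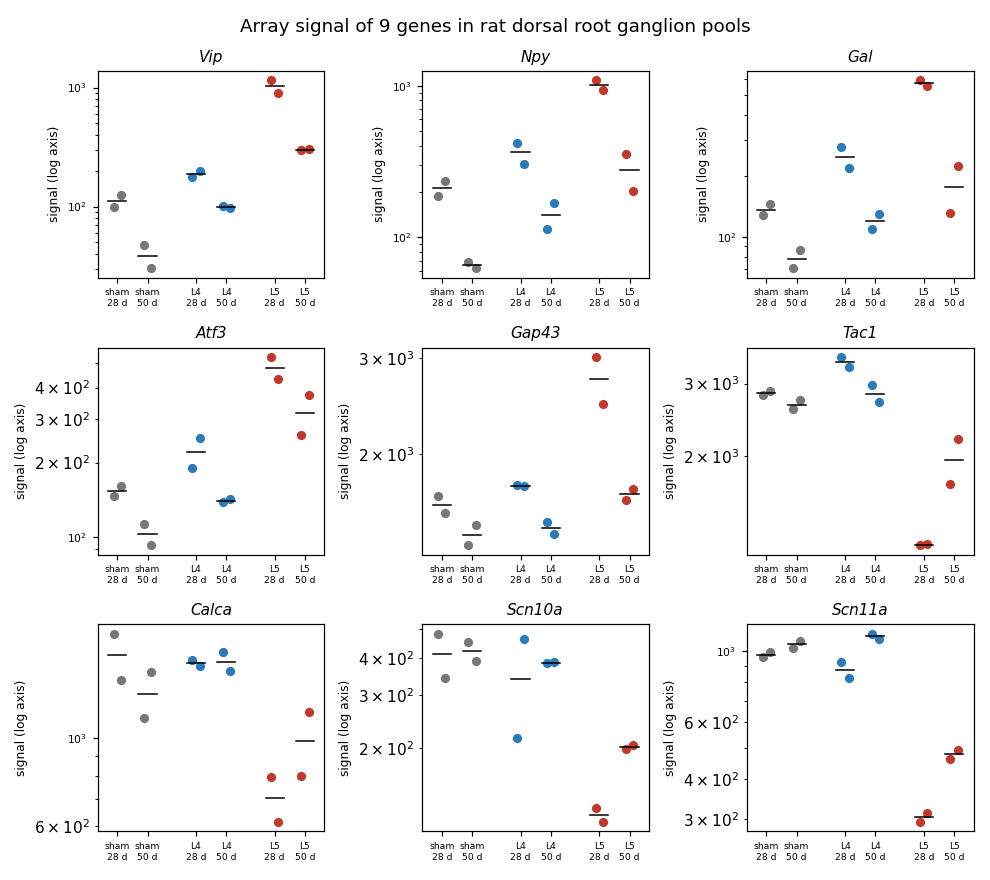
Signal of 9 genes (log axis) on each array of the sham, L4 and L5 pools at 28 and 50 days; points are the 2 arrays of a pool and lines their mean. Vip, Npy and Atf3 lie highest in the L5 pool at each day, and Scn10a and Scn11a lowest.

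Other genes that rose in L5 included immune genes. Cd74, the invariant chain of class II antigen presentation, was higher by 2.03 ± 0.27, although its brightest probe set missed the threshold (0.51 ± 0.31, adjusted p = 0.43) and 1 of its 4 probe sets was lower. The complement component C2 was higher by 1.93 ± 0.23, fibronectin (Fn1) by 1.72 ± 0.33 and the chemokine Cxcl14 by 1.68 ± 0.23. The Fn1 probe set was dim (signal 11.2 in sham at 28 days), and the brighter probe set of Fn1 missed the threshold (0.59 ± 0.30). Sipa1l2 (1.62 ± 0.29), Slfn2 (1.61 ± 0.28), Baiap2 (1.47 ± 0.26) and Cuedc2 (1.39 ± 0.21) completed the 12 largest rises. Adjusted p for these 8 genes lay between 0.015 and 0.046. Without the sham pool of 28 days C2 (2.04), Fn1 (1.59), Cxcl14 (1.65), Sipa1l2 (1.95), Slfn2 (1.68), Baiap2 (1.22) and Cuedc2 (1.30) missed the threshold. Without that of 50 days so did C2 (1.81), Fn1 (1.86), Cxcl14 (1.71), Sipa1l2 (1.29), Slfn2 (1.54), Baiap2 (1.72) and Cuedc2 (1.48). Sipa1l2 (1.22) also missed it without the L5 pool of 50 days, and Baiap2 (1.26) without that of 28 days.

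The largest falls in L5 were those of Tesc, by -1.70 at 28 and -2.31 at 50 days (SE of their mean 0.24), and of the nicotinic receptor subunit Chrna3, to 0.251 of the sham level (SE 0.27 on the log2 scale). Dpysl4 (-1.95 ± 0.25), the RNA editing enzyme Adarb1 (-1.71 ± 0.34), the calcium-sensing receptor Casr (-1.66 ± 0.27) and the potassium channel Kcnd3 (-1.65 ± 0.27, with its other probe set higher) followed. Cdk5 (-1.64 ± 0.29), Tmem59 (-1.60 ± 0.18), Septin8 (-1.58 ± 0.31, with 1 of 4 probe sets higher) and the complement regulator Cd55 (-1.56 ± 0.22, lower in 7 of 7 probe sets) were lower too. Dym (-1.47 ± 0.20) and Abcd2 (-1.41 ± 0.26) completed the 12, whose adjusted p lay between 0.010 and 0.049. Without the sham pool of 28 days Adarb1 (-1.87), Kcnd3 (-1.38), Cdk5 (-1.54), Tmem59 (-1.63), Septin8 (-1.56), Dym (-1.43) and Abcd2 (-1.48) missed the threshold. Without that of 50 days so did Adarb1 (-1.56), Casr (-1.58), Cdk5 (-1.75), Septin8 (-1.60), Dym (-1.51) and Abcd2 (-1.34). Abcd2 (-1.34) also missed it without the L5 pool of 28 days.

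Of the genes named in any case, Cacna2d1, the gabapentin-binding calcium channel subunit (0.90 ± 0.22, adjusted p = 0.078), missed the threshold in L5 against sham. So did Calca, which encodes CGRP (-0.79 ± 0.20, adjusted p = 0.097), and Tac1, which encodes substance P (-0.83 ± 0.22, adjusted p = 0.11). A second probe set of Tac1 was called lower. Gap43 (0.50 ± 0.19, adjusted p = 0.21), Reg3b (0.75 ± 0.45, adjusted p = 0.43) and Trpv1 (-0.37 ± 0.28, adjusted p = 0.52) missed it too, and Gap43 turned to -0.01 when scaled to hybridisation controls. With 1 pool per day, which allows no test at a day, these differences were further from 0 at 28 than at 50 days: 1.35 and 0.45 for Cacna2d1, -1.18 and -0.40 for Calca, and -1.21 and -0.45 for Tac1. They were 0.75 and 0.25 for Gap43, 1.496 and -0.00 for Reg3b, and -0.77 and 0.03 for Trpv1.

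Of the 32 gene lists, 14 passed the camera test in L5 against sham, 7 higher and 7 lower, and 0 passed with an estimated correlation. With 2 residual degrees of freedom the estimated version could hardly pass any list, so that 0 decides little. Each gene is counted in its list by its brightest probe set, so that Cd74, Fn1, Cd55 and Kcna1, called on other probe sets, are not among the called members below. Axon injury and regeneration genes were higher (median 0.51, camera adjusted p = 1.83e-06, adjusted p = 0.346 with an estimated correlation). Of 37 members 4 were called higher (Vip, Npy, Atf3 and Gal), and 12 when adjusted over the list alone. Arg1 stood at 1.51 ± 0.44 without passing. The median was 0.32 without the L5 pool of 28 days.

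Skeletal muscle genes were also higher in L5 (median 0.72, camera adjusted p = 2.80e-06, adjusted p = 0.346 with an estimated correlation). Of 19 members Tpm2 was called (1.16 ± 0.21), and 4 when adjusted over the list alone. Acta1 (1.32 ± 0.50), Tnnc2 (1.28 ± 0.37) and Ckm (1.04 ± 0.31) missed the threshold. At 28 and 50 days they stood at 2.93 and -0.28 (Acta1), 2.21 and 0.36 (Tnnc2), and 1.85 and 0.23 (Ckm). The median of the list against sham was 0.95 at 28 days and 0.23 at 50 days in L5, and 0.38 and -0.05 in L4. In sham it was 0.58 higher at 50 than at 28 days. The L5 median was 0.37 without the sham pool of 28 days and 0.42 without the L5 pool of 28 days. Tpm2 missed the threshold without the sham pools of 28 (0.97) or 50 days (1.35), or the L5 pool of 28 days (0.91).

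Macrophage genes were higher in L5 (median 0.59, camera adjusted p = 0.00011, adjusted p = 0.547 with an estimated correlation), beside the muscle median of 0.72. Of 18 members 17 were above 0 at 28 days and 12 at 50 days, 0 were called, and 1 when adjusted over the list alone. The largest were Cd4 (1.12 ± 0.38), Ctss (1.00 ± 0.35), Fcer1g (0.97 ± 0.21) and Aif1 (0.88 ± 0.42). At 28 and 50 days Cd4 stood at 0.98 and 1.25, Ctss at 1.84 and 0.15, Fcer1g at 1.13 and 0.82, and Aif1 at 1.68 and 0.09. Without the L5 pool of 28 days the macrophage median was 0.17 and the list did not pass (adjusted p = 0.43). It was 0.20 without the sham pool of 28 days and 0.98 without the L5 pool of 50 days.

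Antigen presentation genes (median 0.34, camera adjusted p = 0.00061), cytokines and chemokines (0.29, 0.0023) and complement (0.35, 0.0071) were higher in L5, each with adjusted p = 0.346 with an estimated correlation. With arrays scaled to hybridisation controls, where all probe sets had a median of -0.44, these medians were -0.09, -0.13 and -0.09. Called members numbered 0 of 22, 0 of 21 and 1 of 14 (C2), and 2, 0 and 2 when adjusted over the list alone. Among antigen presentation genes RT1-Da stood at 1.27 ± 0.30, RT1-Ba at 0.78 ± 0.21, RT1-S3 at 0.75 ± 0.24 and RT1-Db1 at 0.68 ± 0.23. At 28 and 50 days RT1-Da stood at 2.08 and 0.46, and RT1-Db1 at 1.17 and 0.19. Among cytokines Il13 stood at 0.97 ± 0.35, Cxcl13 at 0.91 ± 0.37, Il18 at 0.88 ± 0.38 and Il3 at 0.59 ± 0.35 (0.24 at 28 and 0.93 at 50 days). In complement C1qa stood at 0.86 ± 0.36, C1r at 0.84 ± 0.26 and C1s at 0.78 ± 0.40. At 28 and 50 days these stood at 1.77 and -0.06 (C1qa), 1.33 and 0.36 (C1r), and 1.58 and -0.03 (C1s). The cytokine median was 0.47 without the sham pool of 28 days, and the complement median 0.11 without the L5 pool of 50 days. With the filter at the 60th percentile complement (0.35, adjusted p = 0.055) and cytokines (0.20, adjusted p = 0.10) did not pass, nor did complement with only the first array of each pool (0.32, adjusted p = 0.060).

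Extracellular matrix genes were higher in L5 (median 0.31, camera adjusted p = 0.00076, adjusted p = 0.551 with an estimated correlation), with a median of -0.17 when scaled to hybridisation controls. Of 45 members 0 were called, and 5 higher and 1 lower when adjusted over the list alone. Thbs4 stood at 1.19 ± 0.35, Ccn1 at 1.04 ± 0.25, Col5a2 at 0.92 ± 0.23 and Fbln2 at 0.499 of the sham level. Without the L5 pool of 28 days the median was -0.01 and the list did not pass (adjusted p = 0.56), and without that of 50 days it was 0.53.

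The potassium and sodium channel lists were lower in L5. Potassium channels (median -0.30, camera adjusted p = 0.0030, adjusted p = 0.551 with an estimated correlation) had 4 of 32 members called lower and 10 when adjusted over the list alone. These were Kcnd3, Kcnd1 (-1.40 ± 0.18), Kcns1 (-1.24 ± 0.24) and Kcnk1 (-0.97 ± 0.18), while Kcnab1 (-1.29 ± 0.24) missed the threshold. Without the sham pools of 28 and 50 days Kcnd1 (-1.51 and -1.28) and Kcns1 (-1.03 and -1.45) missed it. Without the L5 pool of 28 days the median was -0.07 and the list did not pass (adjusted p = 0.46). The median was -0.17 and -0.67 without the sham pools of 28 and 50 days, and -0.59 without the L5 pool of 50 days. Sodium channels (median -0.23, camera adjusted p = 0.0086, adjusted p = 0.551 with an estimated correlation) had 3 of 10 called lower and 4 when adjusted over the list alone. Scn4b stood at -0.71 ± 0.18. The sodium channel list did not pass without the sham (-0.20, adjusted p = 0.065) or the L5 pool (-0.35, adjusted p = 0.096) of 28 days, and its median was -0.44 without the L5 pool of 50 days.

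The lists of synaptic vesicle genes, general neuronal markers and large-diameter neurons were lower in L5 as well. Synaptic vesicle genes (median -0.29, camera adjusted p = 0.0012, adjusted p = 0.346 with an estimated correlation) had 0 of 32 called and 9 lower when adjusted over the list alone. Rab3c stood at -1.59 ± 0.35, Nsf at -1.10 ± 0.23, Vamp1 at -0.95 ± 0.23 and Syt3 at -0.89 ± 0.18. Their median was -0.19 without the L5 pool of 28 days. General neuronal markers (median -0.25, camera adjusted p = 0.014, adjusted p = 0.346 with an estimated correlation) had 0 of 16 called and 4 when adjusted over the list alone. Rbfox3 stood at -0.97 ± 0.19, Isl1 at -0.78 ± 0.20, Gng3 at -0.60 ± 0.19 and Ncdn at -0.56 ± 0.18. The neuronal list did not pass without the sham (-0.22, adjusted p = 0.090) or the L5 pool (-0.21, adjusted p = 0.082) of 50 days, and stood at -0.41 without the sham pool of 28 days. Markers of large-diameter neurons (median -0.29, camera adjusted p = 0.020, adjusted p = 0.551 with an estimated correlation) had 1 of 17 called (Scn1a) and 4 when adjusted over the list alone. Vsnl1 stood at -1.16 ± 0.33 (-1.94 at 28 and -0.38 at 50 days), Ntrk2 at -0.94 ± 0.18 and Kcna1 at -0.88 ± 0.25. This list did not pass without the sham pool (-0.22, adjusted p = 0.065) or the L5 pool (0.09, adjusted p = 0.78) of 28 days, and stood at -0.51 without the L5 pool of 50 days. With only the first array of each pool it did not pass either (-0.30, adjusted p = 0.054).

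Among metabolic lists, oxidative phosphorylation was lower in L5 (median -0.30, camera adjusted p = 1.14e-06, adjusted p = 0.346 with an estimated correlation), with 0 of 68 called and 15 lower when adjusted over the list alone. Cholesterol synthesis was lower (median -0.44, camera adjusted p = 3.83e-05, adjusted p = 0.346 with an estimated correlation), with 0 of 24 called and 3 lower when adjusted over the list alone. Atp5mc3 stood at -0.93 ± 0.19, Ndufs3 at -0.88 ± 0.24, Ndufb7 at -0.73 ± 0.19 and Ndufa8 at -0.72 ± 0.25. Mvk stood at -1.34 ± 0.40, Srebf1 at -1.15 ± 0.26, Nsdhl at -0.65 ± 0.20 and Scd at -0.63 ± 0.19.

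**Figure D2:**
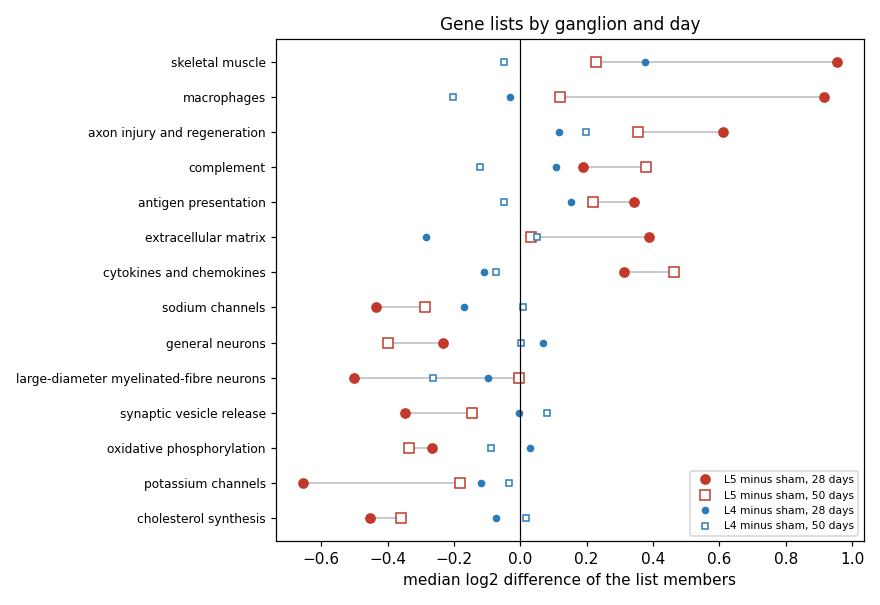
Median log2 difference from sham of the members of the 14 lists that passed the camera test in L5, for L5 (red) and L4 (blue) at 28 days (filled circles) and 50 days (open squares). The macrophage list lies at 0.91 at 28 days and 0.12 at 50 days in L5.

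Other neuronal lists did not pass in L5 against sham. Medians (camera adjusted p) were -0.49 (0.286) for neuropeptides, -0.07 (0.629) for calcium channels and -0.23 (0.444) for transduction and pacemaker channels. They were 0.19 (0.092) for opioid and other G protein-coupled receptors, 0.08 (0.789) for GABA and glutamate receptors and -0.00 (0.629) for neurotrophic factors and receptors. They were -0.16 (0.070) for the neuronal cytoskeleton, -0.37 (0.092) for peptidergic and -0.30 (0.115) for non-peptidergic nociceptors. Sympathetic genes had 0.29 (0.096), and immediate early and heat shock genes 0.19 (0.159). The neuropeptide list went both ways, with Vip, Npy and Gal called higher, Chgb called lower (-0.96 ± 0.18), and 5 higher and 10 lower when adjusted over the list alone. Dpysl4 and Cdk5 were called in the cytoskeleton list and Scn11a among non-peptidergic nociceptors. The calcium channel mean (0.04) and test lay above 0, and the GABA and glutamate mean (-0.03) and test below 0, against their medians.

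Lists of other cell types did not pass in L5 against sham either. Medians were 0.20 for T cells, -0.02 for satellite glia (mean and test above 0), 0.14 for myelinating Schwann cells, 0.24 for repair Schwann cells, 0.16 for blood cells, 0.21 for fat cells and 0.05 for vessel cells. Camera adjusted p lay between 0.073 and 0.47.

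The L4 comparison asks how a neighbour with an intact nerve differs from sham. In limma 0 probe sets passed. At an unadjusted p under 0.05 there were 426, below the 786 that chance alone would give. All conditions share 1 estimate of the spread, and the pools of 28 and 50 days differed most in L5. There 1592 probe sets differed by at least 1 with the arrays of the pools apart, against 476 in sham and 259 in L4. The shared spread may be too wide for L4 against sham, so 0 calls do not show that L4 equals sham. With the pool as a random block over 12 arrays 1 passed, and with 1 pool left out 2 (sham, 28 days), 3 (L4, 28 days), 10 (L5, 28 days), 3 (sham, 50 days), 7 (L4, 50 days) and 9 (L5, 50 days). With arrays scaled to hybridisation controls 5 passed, and the median of all probe sets was 0.20. Npy stood at 0.85 ± 0.22 (unadjusted p = 0.0021, adjusted p = 0.999) and Vip at 0.85 ± 0.24 (unadjusted p = 0.0049, adjusted p = 0.999). Gal stood at 0.67 ± 0.26, Cacna2d1 at 0.54 ± 0.22, Atf3 at 0.44 ± 0.21, Reg3b at 0.18 ± 0.45 and Tac1 at 0.17 ± 0.22. Calca stood at 0.11 ± 0.20, Trpv1 at 0.09 ± 0.28, Gap43 at 0.08 ± 0.19, Scn11a at -0.04 ± 0.19 and Scn10a at -0.23 ± 0.22. The lowest p-values above 0, none past the threshold, were those of Taok2 (1.43 ± 0.22), Flot2 (1.48 ± 0.29), Tuba1a (1.28 ± 0.23), Tex261 (1.11 ± 0.24) and Vdac1 (1.34 ± 0.31). Those below 0 were Bcat2 (-1.66 ± 0.33), RT1-CE16 (-0.74 ± 0.18), Mapk8ip2 (-1.36 ± 0.33, with -0.56 at 28 and -2.15 at 50 days), Hscb (-1.17 ± 0.30) and Kctd6 (-0.77 ± 0.20).

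Of the 32 lists, 2 passed in L4 by the camera test. Axon injury and regeneration genes were higher (median 0.18, camera adjusted p = 0.00050, adjusted p = 0.932 with an estimated correlation), with 0 of 37 called and 2 when adjusted over the list alone. Arg1 stood at 1.24 ± 0.44 and Crem at 0.88 ± 0.37. Without the sham pool of 28 days (0.13, adjusted p = 0.15) or the L4 pool of 50 days (0.08, adjusted p = 0.055) the list did not pass, and without the L4 pool of 28 days its median was 0.28. With only the first array of each pool it did not pass (-0.03, adjusted p = 0.13). Skeletal muscle genes passed narrowly, and not in 11 of 20 alternative settings (median 0.24, camera adjusted p = 0.049, adjusted p = 0.932 with an estimated correlation), with 0 of 19 called and 0 when adjusted over the list alone. Ckm stood at 0.66 ± 0.31, Acta1 at 0.61 ± 0.50, Casq1 at 0.60 ± 0.28 and Tnnt3 at 0.52 ± 0.38. At 28 and 50 days Ckm stood at 1.16 and 0.17, Acta1 at 1.25 and -0.02, and Tnnt3 at 0.84 and 0.21 in L4. Without the sham pool of 28 days the muscle median was -0.10 and without the L4 pool of 28 days 0.15, and the list did not pass. It was 0.48 without the sham and 0.38 without the L4 pool of 50 days. The muscle list also did not pass with quantile normalization (0.21), median centring (0.23), the median pseudocount (0.16), no filter (0.25), no intensity trend (0.24) or only the first array of each pool (0.19). Nor did it with all hybridisation controls (0.37) or without the least correlated arrays (0.24). Among lists that did not pass, blood cells (median -0.05, mean 0.15), GABA and glutamate receptors (-0.00, 0.02), neurotrophic factors (0.01, -0.02) and sympathetic genes (-0.02, 0.02) had medians and means of different sign.

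Against L4, the L5 ganglia again had higher Vip, Npy and Atf3 and lower Scn11a and Scn10a. Vip differed by 1.88 ± 0.24 (adjusted p = 0.019), Npy by 1.18 ± 0.22 (adjusted p = 0.031), Atf3 by 1.08 ± 0.21 (adjusted p = 0.037), Scn11a by -1.34 ± 0.19 (adjusted p = 0.019) and Scn10a by -1.10 ± 0.22 (adjusted p = 0.039). Cxcl14 (2.21 ± 0.40, on another probe set than against sham), Cd74 (1.72 ± 0.27), Medag (1.58 ± 0.27), Emp1 (1.54 ± 0.28) and Hscb (1.53 ± 0.30) were higher. So was a probe set annotated as Rpl19l4 (1.38 ± 0.23), a doubtful name, since it is 1 of 16 repeat-like probe sets, most of which moved together. Gnas was called higher on 1 probe set (1.48 ± 0.18) and lower on another (-0.92), so it has no direction here. Cd55 (-1.89 ± 0.22), the calpain inhibitor Cast (-1.87 ± 0.36), Cdk5 (-1.87 ± 0.29) and the axonal adhesion molecule Cntn1 (-1.85 ± 0.32) were lower. So were Septin8 (-1.82 ± 0.31), Kcnd3 (-1.79 ± 0.27), Tmem59 (-1.78 ± 0.18) and Chrna3 (-1.76 ± 0.27). Tac1 (0.499 of the L4 level, adjusted p = 0.054), Calca (-0.91 ± 0.20, adjusted p = 0.055), Gal (0.83 ± 0.26, adjusted p = 0.13), Trpv1 (-0.47 ± 0.28) and Reg3b (0.57 ± 0.45) missed the threshold. So did Gap43 (0.42 ± 0.19) and Cacna2d1 (0.36 ± 0.22), which were below 0 with arrays scaled to hybridisation controls. At 28 and 50 days Gap43 stood at 0.64 and 0.20, Cacna2d1 at 0.56 and 0.16, Trpv1 at -0.79 and -0.14, and Reg3b at 0.97 and 0.16.

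In all, 203 probe sets passed in L5 against L4, 43 higher and 160 lower. The count was 112 without the L4 pool of 28 days, 640 and 790 without the L5 pools of 28 and 50 days, and 0 without the intensity trend. With arrays scaled to hybridisation controls it was 6722, of which 19 were higher, and the median of all probe sets was -0.64. Without the L4 pool of 28 days Vip (1.56), Npy (0.99), Atf3 (1.10), Scn10a (-1.05), Cxcl14 (1.74), Emp1 (1.18), Hscb (1.89), Cast (-2.08), Cntn1 (-1.54) and Septin8 (-1.53) missed the threshold. So did Hscb (1.17) and Cast (-1.66) without the L4 pool of 50 days, Hscb (1.16) without the L5 pool of 50 days and Cxcl14 (1.58) without that of 28 days, where Emp1 stood at 0.97.

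By camera 17 lists passed in L5 against L4, 9 higher and 8 lower, and 0 with an estimated correlation (adjusted p = 0.346 with an estimated correlation at the lowest). Higher were macrophages (median 0.76, camera adjusted p = 3.87e-05), skeletal muscle (0.48), extracellular matrix (0.44), antigen presentation (0.36), axon injury and regeneration (0.35), complement (0.31), cytokines and chemokines (0.29), G protein-coupled receptors (0.28) and myelinating Schwann cells (0.25). All of these but the macrophage list had medians below 0 with arrays scaled to hybridisation controls. All probe sets then had a median of -0.64. Against other genes the camera test of these lists stayed above 0 and passed, except for myelinating Schwann cells (camera adjusted p = 0.16 with all controls). Lower were peptidergic nociceptors (-0.47), cholesterol synthesis (-0.34), oxidative phosphorylation (-0.26), potassium channels (-0.26), general neurons (-0.26), the neuronal cytoskeleton (-0.23), sodium channels (-0.20) and synaptic vesicle genes (-0.13). Without the L5 pool of 28 days 9 lists passed. Those of macrophages (0.35), skeletal muscle (0.20), matrix (0.25), antigen presentation (0.31), axon injury (0.02), Schwann cells (0.19), peptidergic nociceptors (-0.21), potassium channels (0.02) and sodium channels (-0.28) did not. Without the L4 pool of 28 days matrix (0.18), Schwann cells (0.16), peptidergic nociceptors (-0.34) and potassium channels (-0.14) did not pass. G protein-coupled receptors did not pass without the L4 (0.07) or the L5 pool (0.05) of 50 days, nor general neurons (-0.30) without the latter. Complement, which passed with each pool left out, ranged from 0.04 without the L5 pool of 50 days to 0.56 without the L4 pool of 28 days and was 0.11 without that of 50 days.

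Other settings ended calls of lists in L5 against L4 too. In all, myelinating Schwann cells did not pass in 8 of 20 settings, G protein-coupled receptors in 7, and sodium channels, potassium channels and peptidergic nociceptors in 6 each. Schwann cells did not pass with median centring (0.06), no filter (0.25), only the first array of each pool (0.16), or hybridisation controls with (-0.38) and without Cre (-0.41). G protein-coupled receptors did not with quantile normalization (0.14), no filter (0.12), only the second array of each pool (0.18) or without the least correlated arrays (0.21). Sodium channels did not with no filter (-0.11), no intensity trend (-0.20), all hybridisation controls (-0.86) or without the least correlated arrays (-0.20). Potassium channels did not with no filter (-0.03) or hybridisation controls with (-0.78) and without Cre (-0.81). Peptidergic nociceptors did not with only the second array of each pool (-0.39), all hybridisation controls (-1.04) or without the least correlated arrays (-0.34). With the filter at the 60th percentile complement (0.31) and cytokines (0.26) did not pass.

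Medians of other lists that still passed in L5 against L4 moved as well. Without the L4 pool of 28 days that of macrophages was 0.49, of G protein-coupled receptors 0.48, of sodium channels -0.41 and of synaptic vesicle genes -0.30. Without that of 50 days the matrix median was 0.67, that of antigen presentation 0.23 and that of synaptic vesicle genes -0.20. Without the L5 pool of 28 days G protein-coupled receptors had 0.53, cytokines 0.45 and synaptic vesicle genes -0.27. Without that of 50 days skeletal muscle had 0.80, potassium channels -0.44, sodium channels -0.31 and synaptic vesicle genes -0.26. Among lists that did not pass, GABA and glutamate receptors (median 0.08, mean -0.05) and neurotrophic factors (0.02, -0.00) had medians and means of different sign.

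From 28 to 50 days the haemoglobin genes Hbb and Hbb-b1 fell, with the same sign in each of the 3 conditions. Hbb (-2.05 ± 0.17, adjusted p = 0.00036) and Hbb-b1 (-1.89 ± 0.15, adjusted p = 0.00036), the haemoglobin beta chains, and S100a9, a neutrophil protein (-2.03 ± 0.26, adjusted p = 0.0092), were lower at 50 days. So were Cxcl14 (-2.43 ± 0.33, adjusted p = 0.012, with 1 of 3 probe sets higher) and Emp1 (-1.66 ± 0.23, adjusted p = 0.025, with 1 of 2 higher). The Cxcl14 probe set called in L5 against sham is another one, with 0.14 in sham and 0.21 in L5 between the days. S100a8 (0.10 ± 0.21) and Defa5 (-0.56 ± 0.34), in the blood cell list with S100a9, were not called. Npy (-1.55 ± 0.18) and Vip (-1.22 ± 0.19) were called lower too. Fn1 was called lower on its brighter probe set (-1.53 ± 0.25), while the one called in L5 against sham stood at 1.03 ± 0.27. Pip (1.34 ± 0.23), Ntn3 (1.23 ± 0.18), Cdk16 (1.12 ± 0.18) and a repeat-like probe set annotated as Crp, also a doubtful name (1.07 ± 0.17), were higher, and Aph1a (0.89 ± 0.17, adjusted p = 0.066) missed the threshold. Ntn3 missed it without the sham pool of 28 or 50 days (1.24 in both), and Cdk16 without the L5 pool of 28 or 50 days (0.99 in both).

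Between the days 45 probe sets passed, 16 higher and 29 lower, and 0 without the intensity trend. The count was 111, 439 and 69 without the sham, L4 and L5 pools of 28 days, and 97, 454 and 70 without those of 50 days. The counts without the 28 day and the 50 day pool of a condition rest on the same pools of the other conditions, so they are nearly the same check. Day and collection cannot be told apart with 1 pool per condition and day. By camera 11 lists passed, 6 higher and 5 lower, and 0 with an estimated correlation. The matrix list was lower (median -0.45, camera adjusted p = 9.00e-10, adjusted p = 0.713 with an estimated correlation), with medians of -0.45 in sham, -0.10 in L4 and -0.76 in L5. It had 5 of 45 called, among them Col3a1 (-1.56 ± 0.20) and Lum (-1.35 ± 0.20), and 17 lower and 2 higher when adjusted over the list alone. The blood cell list was lower (median -0.56, camera adjusted p = 3.12e-06, adjusted p = 0.713 with an estimated correlation), with 3 of 7 called and 4 when adjusted over the list alone. Repair Schwann cells (-0.25), axon injury (-0.16, with -0.11 in sham, 0.00 in L4 and -0.46 in L5) and oxidative phosphorylation (-0.15) were lower. Sympathetic genes (0.33), T cells (0.31), large-diameter neurons (0.27), potassium channels (0.25), G protein-coupled receptors (0.23) and the cytoskeleton (0.20) were higher, each of these 9 with adjusted p = 0.713 to 0.726 with an estimated correlation.

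Most day lists lost their call in several of 20 settings (19 for sympathetic genes), among them 7 for sympathetic genes, 6 each for axon injury, large-diameter neurons, G protein-coupled receptors and oxidative phosphorylation, 5 each for the cytoskeleton and T cells, and 4 for potassium channels. Without the L5 pool of either day, potassium channels (0.07), axon injury (-0.08), large-diameter neurons (0.07), sympathetic genes (0.20) and G protein-coupled receptors (0.07 and 0.08) did not pass, and the cytoskeleton (0.10) did not without that of 28 days. Oxidative phosphorylation (-0.10) did not pass without the L4 pool of either day. Once 1 pool of a condition is left out, its other pool holds no information on the day. Leaving out either pool is therefore nearly the same check. A call lost in both is counted for each, so the counts of settings overstate the distinct checks lost. Without the L4 pool of either day the matrix median was -0.74, that of T cells 0.47 and that of axon injury -0.26, and without either sham pool that of sympathetic genes was 0.61. With quantile normalization G protein-coupled receptors (0.13), axon injury (-0.07), oxidative phosphorylation (-0.07) and sympathetic genes (0.27) did not pass. With only the first array of each pool sympathetic genes (0.30), the cytoskeleton (0.17) and large-diameter neurons (0.25) did not, and with only the second G protein-coupled receptors (0.25), axon injury (-0.16), oxidative phosphorylation (-0.09), T cells (0.37) and potassium channels (0.14). The same held for T cells (0.19) and sympathetic genes (0.30) with no filter, T cells (0.28) and large-diameter neurons (0.22) with the 60th percentile filter, and the cytoskeleton (0.09) and large-diameter neurons (0.13) with median centring. It held for axon injury (-0.16) with no intensity trend, oxidative phosphorylation (-0.19) with all hybridisation controls and the cytoskeleton (0.18) with those without Cre. Without the least correlated arrays G protein-coupled receptors (0.26), sympathetic genes (0.35) and T cells (0.29) did not pass. The cytoskeleton, which still passed without the L5 pool of 50 days, had 0.10 there too. Neuropeptides (median 0.09, mean -0.06), satellite glia (0.03, -0.02) and immediate early genes (0.03, -0.03) did not pass between the days and had medians and means of different sign.

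The L5 effect was partly shared between days. Across 15721 probe sets, which are not independent replicates, the L5 minus sham difference at 28 days correlated with that at 50 days at r = 0.320 (Spearman 0.331), and 62.3% had the same sign. A rule of size asked for a log2 difference of at least 1 with both arrays of a pool outside those of the other, a separation that chance gives in 33.3%. By it 57 probe sets were higher and 60 lower at both days and 13 went opposite ways, where independent lists would share 13.1 and 8.93. In L4 the correlation was 0.0097 (Spearman -0.0026) and 49.8% had the same sign. By the rule of size 4 probe sets were higher and 7 lower at both days in L4 and 8 went opposite ways, where independent lists would share 1.496 and 0.784.

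RNA quality as read from 3' to 5' ratios differed between pools, more by GAPDH than by beta-actin. The ratio of 3' to 5' GAPDH probe sets averaged 8.18 ± 2.11 (SD, 6 arrays) in sham at 28 days and 6.84 ± 1.29 in sham at 50 days. It was 4.67 ± 0.79 and 3.94 ± 0.74 in L5, and 4.96 ± 1.72 and 5.78 ± 0.58 in L4. The beta-actin ratio at 28 and 50 days was 5.17 ± 0.48 and 4.84 ± 0.97 in sham. In L5 it was 3.95 ± 0.91 and 4.09 ± 0.78, and in L4 3.90 ± 0.71 and 4.94 ± 0.94. By both ratios the means of both L5 pools lay below those of both sham pools. RNA quality thus goes with the comparison of L5 and sham, and its part in the calls and lists of that comparison was not tested. Arrays of the L5 pool at 50 days correlated least with their duplicates (mean r = 0.904). The array of each chip type that correlated least with arrays of other pools also came from that pool. Leaving these arrays out left 93 calls for L5 against sham, of which 79 were among the 123. This choice can fall on an array that is unlike the other conditions as well as on one of poor quality.

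The bacterial hybridisation controls were brightest on L5 arrays. Their mean log2 signal was 10.35 ± 0.17 (SD, 6 arrays) and 10.45 ± 0.15 in L5 at 28 and 50 days, 9.94 ± 0.23 and 9.79 ± 0.35 in sham, and 9.52 ± 0.11 and 9.76 ± 0.09 in L4.

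**Figure D3:**
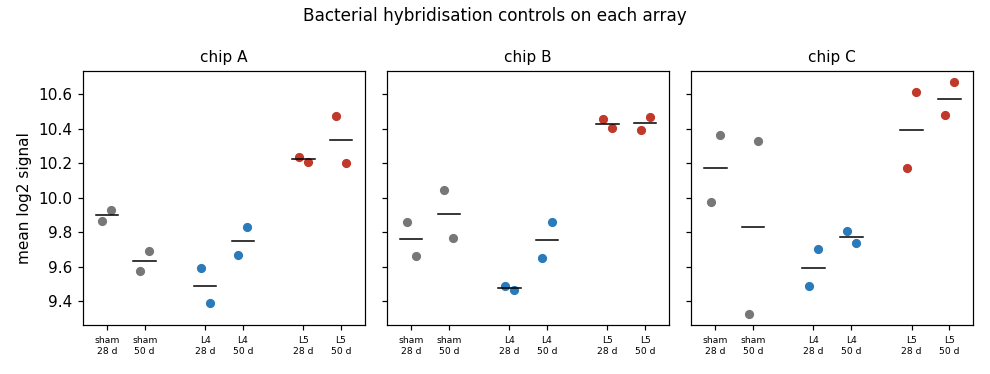
Mean log2 signal of 9 bacterial hybridisation control probe sets on each array, by chip type, condition and day; lines are means of the 2 arrays of a pool. The L5 pools average 10.35 at 28 days and 10.45 at 50 days, above the sham and L4 pools.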

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

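All tests in this part but that of a lone array were chosen after their results, or the values behind them, were seen.

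For 5 named genes the L5 effect differed between the days in a limma fit that uses the arrays of a pool as replicates, so that its p-values measure technical spread only. The L5 minus sham difference was 1.84 at 28 and 0.15 at 50 days for Ctss (change -1.69), 1.58 and -0.03 for C1s (change -1.61), and 2.08 and 0.46 for RT1-Da (change -1.62). It was 2.93 and -0.28 for Acta1 (change -3.21), and -1.94 and -0.38 for Vsnl1 (change 1.56). In all, 68 of 15721 probe sets differed, 13 rising and 55 falling, and 0 of them were among the 123 called in L5. That 0 is close to fixed in advance, since a difference between the days enlarges the residual of the main fit.

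For this pattern a sham pool out of place at 28 days is argued against as a common cause, since L4 against the same pool showed a median share of -0.0762 of the L5 difference. The share ran from -0.46 for C1s to 0.42 for Acta1, whose sham signal itself was 187 at 28 and 540 at 50 days, so for Acta1 the sham pool stays open. A lone array out of place also stays open: both L5 arrays lay outside both sham arrays in 5 of the 5 genes, but choosing genes against the spread of these arrays all but fixes that outcome, so the test planned for it decides nothing. Skeletal muscle in the L5 pool of 28 days may account for Acta1, as the muscle list, of whose 19 genes 1 is in another list, stood at a median of 0.95 at 28 days and 0.23 at 50 days, with Acta1 at 1490, Ckm at 352 and Tnnc2 at 259 in that pool against 187, 86.8 and 47.2 in sham. It stays open, as does a response of L5 that fades between the days, because there is 1 L5 pool per day and the sham pools differ in muscle genes too.

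The bacterial hybridisation controls, which are outside the comparisons, were brighter on L5 than on sham arrays, by 0.53 on average over the 3 chip types (0.51, 0.60 and 0.48), and both L5 arrays exceeded both sham arrays in 5 of the 6 chip types and days. With arrays scaled to all controls 21 of the 37 probe sets called higher were still called, and 17 of them also without Cre, with a median of 1.17. These 17 were picked by passing. With 2867 probe sets past the threshold (2085 without Cre), larger p-values pass than before. Their passing therefore does not decide whether scaling was their whole cause, which stays open. All 37 stayed above 0 with all controls (median 0.87, lowest 0.41), so scaling to the controls took away a part of their size. For the other 20 scaling stays open too: their median went from 1.19 (median SE 0.21) to 0.68 (0.31), and calls ended as the difference shrank and its error grew. With arrays scaled to the controls the 86 called lower had a median of -1.62 (-1.60 without Cre), but scaling to controls that are brighter on L5 arrays can only lower L5, so this decides nothing. Less labelled RNA on the L5 arrays may lie behind the brighter controls. Why there would be less cannot be told here, because the brightness goes with the ganglion in every chip type. These controls do not measure RNA per cell.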

How the results depend on the processing

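Counts of calls depended on most choices. Values as deposited changed no count, but this setting moves almost nothing. For L5 against sham (123 as reported), L5 against L4 (203) and the days (45), quantile normalization gave 42, 53 and 15, median centring 423, 674 and 97, no filter 31, 19 and 23, and no intensity trend 4, 0 and 0. The cause was not tested. For these 3 and L4 against sham (0 as reported), the pool as a random block over 12 arrays gave 1113, 1380, 1026 and 1, and arrays as separate replicates, which counts technical spread only, 1564, 1956, 1777 and 1. With the replicate block these became 1437, 1784, 1502 and 1. Across tested probe sets the array numbers showed little pairing. Differences between the 2 arrays correlated over 0.1 in 1, 0 and 0 of 15 pairs of pools on chips A, B and C. On chip C a Cre control probe set was brighter on the second array of every pool (8323 and 19283 in sham at 28 days). There the numbers did go with a difference between arrays. With 1 array per pool, L5 against sham gave 1 to 2 calls, L5 against L4 0 to 1 and the days 2 to 5. With 1 pool left out, the lone pool being assumed to vary like the others, counts ran from 31 (sham, 28 days) to 621 (L5, 50 days) for L5 against sham, 2 to 10 for L4, 112 (L4, 28 days) to 790 (L5, 50 days) for L5 against L4 and 69 to 454 for the days. With only the conditions compared, L5 and L4 against sham gave 435 and 7.

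Chosen after seeing the data, scaling to all hybridisation controls gave 2867, 6722, 272 and 5 calls, and without Cre 2085, 6811, 250 and 14, nearly all lower where L5 was compared. The median of all probe sets was then -0.44 and -0.41 in L5 against sham. Leaving out the least correlated arrays gave 91 for L5 against L4. Other alternatives stayed within 1.5 times.

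The correlation of the L5 effect between days (0.320) was 0.293 with quantile normalization, 0.288 and 0.370 with pseudocounts of 1 and the median, 0.220 with no filter, 0.410 with the 60th percentile filter, 0.184 to 0.259 with 1 array per pool, and 0.269 and 0.286 with the controls with and without Cre. That of L4 was -0.0093 with all controls. Lists past camera in L5 against sham (14), L4 against sham (2), L5 against L4 (17) and the days (11) fell to 0, 0, 0 and 0 with an estimated correlation. That version rests on 2 residual degrees of freedom and could hardly pass any list. L4 lists numbered 1 with median centring, with the median pseudocount, with no filter, with no intensity trend and without the least correlated arrays, 4 with the 60th percentile filter, 5 and 6 with the controls with and without Cre, 0 to 2 with 1 array per pool and 1 to 4 with 1 pool left out. With 1 pool left out, lists ran from 9 to 20 for L5 against L4 and 6 to 13 for the days, and with 1 array per pool from 7 to 8 for the days. Medians of complement, antigen presentation, cytokine and matrix genes in L5 against sham turned negative with either control scaling, while their test against other genes stayed above 0. Over 145 differences of named genes and 3728 recomputed values, 0 called values changed sign, 344 lost and 368 gained the threshold, and 26 uncalled values changed sign. Detection calls were not used, so signal over background limits the dim genes to an unknown degree.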

Other observations

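The tests in this part on the repeat-like probe sets were chosen after the result was seen; the splits of the pools were planned.

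A group of 16 probe sets on chip A, most without a gene name and several with a suffix for sequence families, largely moved together. In L5 at 50 days 1 of them lay below sham (-1.96), and it stood at -0.30 in L5 against sham and -0.05 between the days. The group was picked out after its values were seen. In L5 against sham 11 of the 16 were called (median 1.15) and in 50 against 28 days 10 were called (median 0.96), so that they make up 29.7% of the 37 probe sets higher in L5. Probe sets annotated as Crp and Rpl19l4 belong to it, and such probe sets can share sequence with many transcripts, so those names are doubtful. Array scaling as read from the hybridisation controls is argued against for the rise between the days in sham. There the group was higher at 50 days by a median of 1.16 while the chip A controls were lower (-0.26). For the rise in L5 scaling stays open, as the chip A controls were 0.51 brighter on L5 than on sham arrays. RNA length bias as read from GAPDH stays open: L4 at 28 days, with a ratio 1.48 times below that of sham at 28 days, lay a median of 0.22 above it in the group, but this is 1 pool, and L4 at 50 days and L5 at 28 and 50 days, with ratios 1.44, 1.68 and 1.97 times below, lay 0.95, 1.31 and 2.13 above it. Shared sequence and a response to nerve injury or time stay open and were not tested.

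With the 6 pools split 3 against 3, the day split called 45 probe sets and the highest of the other 9 splits 35. There were 2 splits with 35, both with the sham pools on one side and the L4 pools on the other. With condition as a term of the fit, both rest on the L5 pools of 28 and 50 days alone. They are the same comparison with its sign turned, and it is a day difference itself, so they do not measure chance. Of the 10 splits 1 reached the real count, and 10 splits are too few for a share under 0.05. Other splits that keep both pools of a condition on one side repeat each other in the same way, so the 10 are not all distinct.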
